A study of Mus musculus with 4 samples.

How the data were processed

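RNA of 3T3-L1 adipocytes treated for 7 days with PBS, daidzein, PT or daidzein+PT was hybridized to 1 Agilent mouse array per group, per the labels. The scanner files hold a spot intensity on the linear scale that Agilent Feature Extraction subtracted for background and detrended within each array, per the file headers. They also hold the raw mean intensity of each spot and the median of its local background, per the file headers. The deposited flags (well above background, saturated, outlier, control type) were set by Feature Extraction, per the file headers. The headers give Feature Extraction version 10.7.1.1, whereas the submitters' processing notes give 9.5.1.1. The deposited series table holds an intensity on the linear scale; that it was quantile normalized between arrays was read from its values, since the sorted values of its columns differed by at most 0.0474% (median 18.3 in each). Its columns had a Spearman correlation of at least 0.9999 with their own array and of at most 0.948 with any other. These values were used only as an alternative.

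The arrays carried 62976 spots each. Control spots and outlier spots were left out (106 for PBS, 131 for daidzein, 156 for PT and 173 for daidzein+PT). The processed signal was put on the log2 scale and the 75th percentile of the array's non-control probes was subtracted. That percentile was 372 for PBS, 406 for daidzein, 418 for PT and 360 for daidzein+PT. Replicate spots of a probe (432 probes) were averaged, and a gene was represented by its probe with the highest mean signal. Of 55681 probes, 27235 had an accession in a reference table of gene names (GRCm38), used only for names, and 2838 were renamed from it. Probe positions are those of the files, on mm9. Labelling was checked with the spike-in spots, whose slopes of signal on amount were 0.92 for PBS, 0.90 for daidzein, 0.99 for PT and 0.99 for daidzein+PT, per the file headers. Scaled differences between arrays were taken from 6 spike-in probes.

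The 5 comparisons were PT over PBS, daidzein over PBS, daidzein+PT over PBS, daidzein+PT over daidzein and daidzein+PT over PT. A gene entered a comparison when it was well above background on both arrays, and genes at 2-fold or more were counted. With 1 array per group no test was made for a comparison. A gene well above background on only 1 of the 2 arrays gave a bound, taken as the difference from the other array's own value or from the dimmest spot well above background there, whichever was brighter. Each treatment was compared in 2 pairs that share no array, and the number of genes in both lists was set against the number independent lists would share. The interaction was the PT difference with daidzein minus the PT difference without it. Its SD over genes, scaled to a difference of 2 arrays, was the measure of spread. An additive model of both treatments was fitted with limma (lmFit, eBayes with an intensity trend, Benjamini-Hochberg adjusted p) to the 19568 genes well above background on at least 2 arrays, with 1 residual degree of freedom, which takes any interaction as error.

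Median differences of 26 gene lists and 5 cell type lists were placed among 10000 random lists of the same size matched on signal in 10 bins. The percentile describes these arrays and is not a test between treatments, and some genes are members of more than 1 list. The text names Adipoq, and for each treatment the 10 genes higher and the 10 lower with the largest smaller difference of its 2 pairs. It also names the 10 highest and the 10 lowest genes for daidzein+PT over PBS, the 5 most positive and 5 most negative interactions, and the 3 highest and 3 lowest bounds that are 2-fold in both pairs of a treatment. For each list up to 4 members with the largest differences are named, with the reference genes. Some genes that these rules select are not reported here. Named genes other than bounds and list members have a gene symbol and signal well above background on all 4 arrays. These rules and the lists were fixed before the data were examined. The genes drawn as lines in the figure of levels were chosen among the named genes after their values were seen, and 1 of the genes first drawn was exchanged because the rules did not name it.

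The procedure was tested on simulated data of 18256 genes with 4 arrays. For PT over PBS, 99 of 100 genes simulated at 4-fold and 25 of 100 at 2-fold, the threshold itself, were at 2-fold or more in both PT pairs, and 0 unchanged genes were. Noise was drawn separately for each gene and array. The simulation therefore holds no effect of slide position or culture that both PT pairs could share. In the same simulation 69 unchanged genes were at 2-fold in PT over PBS alone. Of 200 lists with no shift, 9 lay outside the middle 95% of random lists, and 50 of 50 shifted lists lay above it. The additive limma fit called 94 of the genes at 2-fold and 100 at 4-fold for PT, with 4 unchanged genes. Without the trend it called 39 and 90, with 0 unchanged genes.

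Alternatives were quantile normalization, cyclic loess, median scaling, normexp background correction (offset 50), a filter on all 4 arrays, no filter, the mean over a gene's probes, the authors' table, thresholds of 1.5-fold and 3-fold, limma without a trend, and lists without their largest member. A restriction to the brighter genes was added after the data were seen. Calculations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Position of probes within exons and transcripts was not analysed here.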

Results

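Gene expression was measured in 3T3-L1 cells, a mouse fibroblast line that can be differentiated into adipocytes in culture. The differentiated cells received PBS, the soy isoflavone daidzein (25 uM), an extract of pig testis (PT, 100 ug/ml) or daidzein together with PT for 7 days. Each of the 4 groups was read on 1 single-colour (Cy3) oligonucleotide array of 60-base probes, and the series asks whether PT alters adiponectin expression. Each array held 59305 non-control spots for 55681 probes. The share of these spots well above background was 50.7% for PBS, 51.2% for daidzein, 51.4% for PT and 49.7% for daidzein+PT, and no spot was saturated. Of 34795 genes, 18256 were well above background on all 4 arrays. There were no replicates, so differences between arrays carry no p-value, and the precision is limited by the number of arrays. The 4 arrays lay on 1 slide, PBS and daidzein in row 1 (columns 3 and 4) and PT and daidzein+PT in row 2 (columns 1 and 2). PT and slide position therefore cannot be told apart. Each array with daidzein lay in the column next to its comparison array, so a difference between columns is part of both daidzein pairs.

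The layout gave each treatment effect in 2 pairs with no array in common. The difference between these pairs (the interaction) was the only measure of spread between arrays, and any true dependence of 1 treatment on the other is part of it. Its spread over genes corresponds to an SD of 0.22 for a log2 difference between 2 arrays, with 0.33 among the 6086 dimmest genes, 0.14 among the 6084 of middle signal and 0.11 among the 6086 brightest. This spread alone would place 44 genes at 2-fold higher and 39 at 2-fold lower in a pair of arrays. In the 2 PT pairs 131 and 149 of the same genes were at least 2-fold higher and only 8 and 16 lower. Among the 245 genes with an interaction of 2-fold or more, the array farthest from the gene's median was daidzein+PT for 105, PT for 74, daidzein for 36 and PBS for 30. Departures were thus uneven between arrays, and the spread is not a gauge of what noise places on either side. Replicate spots of a probe within an array had a median SD of 0.05 on the log2 scale.

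Adiponectin mRNA (Adipoq), the adipocyte hormone named by the series, was higher on every treated array than on the PBS array. It was 2.11-fold higher with PT, 4.96-fold higher with daidzein and 8.90-fold higher with both (log2 differences 1.08, 2.31 and 3.15, SD of a difference 0.11). Adding PT to daidzein gave a log2 difference of 0.84, against 1.08 without daidzein, and adding daidzein to PT gave 2.07. The interaction was -0.24. The Adipoq probe lies on chromosome 16 from 23157576 to 23157635 (mouse build mm9); whether it lies in an exon or a UTR was not analysed here.

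**Figure D1:**
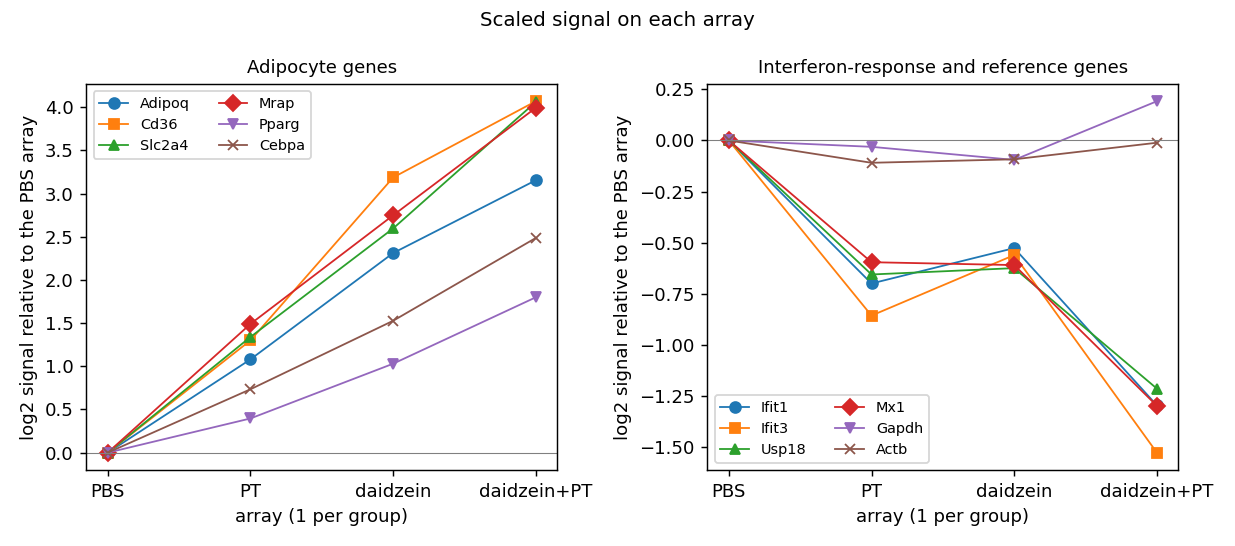
Scaled log2 signal relative to the PBS array (y axis) on each of the 4 arrays (x axis) for 6 adipocyte genes (left) and for interferon-response and reference genes (right), 1 array per group; lines only join the values of a gene. Adipoq lies at 1.08, 2.31 and 3.15 on the PT, daidzein and daidzein+PT arrays, and Ifit3 at -0.86, -0.56 and -1.53.

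PT over PBS addresses the effect of the extract alone. Most listed genes of the mature adipocyte were higher and interferon-response genes were lower on the PT array. Among PPARg target and mature adipocyte genes the median was 1.90-fold higher (log2 0.93, 27 of 31 genes above 0, percentile 100 among 10000 random lists), and 13 of the 29 genes read on both arrays were at least 2-fold higher. Mrap, an accessory protein of the melanocortin receptors, had a log2 difference of 1.49, the glycerol-phosphate dehydrogenase Gpd1 1.46, the lipid-droplet coat protein Plin1 1.39 and the insulin-responsive glucose transporter Slc2a4 1.34. Lipolysis and lipid droplet genes had a median of 0.39 (12 of 17 above 0, percentile 100), with Cidec at 1.33, the lipase inhibitor G0s2 at 1.26 and the monoglyceride lipase Mgll at 1.21. Adipokines and secreted adipocyte proteins had a median of 0.24 (11 of 18 above 0, percentile 100), led by resistin (Retn, 1.32), Cfd (adipsin, 1.11), Adipoq and haptoglobin (Hp, 1.08). Cholesterol synthesis genes had a median of 0.22 (20 of 23 above 0, percentile 100) and fatty acid synthesis genes 0.16 (18 of 20 above 0, percentile 100), with Scd1 at 1.20 and Thrsp at 1.17. All 23 measured interferon-response genes were below 0, with a median of -0.29 (percentile 0). Rsad2 had a log2 difference of -0.89, Ifit3 -0.86, the chemokine Cxcl10 -0.81 and the GTPase Mx2 -0.79, and no member reached 2-fold lower. Counted over all genes, 165 of 18805 were at least 2-fold higher and 12 at least 2-fold lower. Of the 165, 123 were in the dimmest 6268 genes, and with normexp background correction 42 were higher and 1 lower. Quantile normalization gave 140 higher and 30 lower, and the mean over probes 204 and 22. The lipolysis median was 0.16 with normexp, and the adipokine median was 0.12 with the mean over a gene's probes.

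With daidzein already present (daidzein+PT over daidzein), the adipocyte and interferon lists again lay above and below 0, whereas cell cycle genes, at -0.04 with PT alone, lay at 0.20. All 31 PPARg target and mature adipocyte genes were above 0, with a median of 0.80 (percentile 100), and 22 of 23 interferon-response genes were below 0, with a median of -0.50 (percentile 0). The genes with the largest difference in the same direction in both PT pairs, given with daidzein absent and then present, began with the amino acid transporter Slc36a2 (1.77 and 1.41), Slc2a4 (1.34 and 1.46) and Mrap (1.49 and 1.25). Mgll (1.21 and 1.23), Klra5 (1.20 and 1.46), the apolipoprotein Apoc4 (1.19 and 1.26), Aatk (1.45 and 1.19), G0s2 (1.26 and 1.16), the carboxylesterase Ces1f (1.15 and 1.21) and the chitinase-like protein Chil3 (1.25 and 1.14) followed. Most of the 10 lowest genes are known as interferon-inducible, among them Ifit3 (-0.86 and -0.97), Tgtp2 (-0.87 and -0.77), Ifit1 (-0.70 and -0.77), Mx2 (-0.79 and -0.65), Igtp (-0.69 and -0.65), Mx1 (-0.59 and -0.69), Usp18 (-0.65 and -0.59) and Cmpk2 (-0.52 and -0.65). The phosphatase Dusp2 (-0.54 and -0.57) and the antigen-trimming peptidase Erap1 (-0.55 and -0.51) completed the 10. In this pair 203 genes were at least 2-fold higher and 19 at least 2-fold lower, against 65 and 2 with normexp. Among the 18256 genes read on all 4 arrays, 131 and 149 were at least 2-fold higher in the 2 PT pairs and 29 in both, where independent lists would share 1.07, and 1 gene was at least 2-fold lower in both; across genes, which are not independent replicates, Pearson's r was 0.23. With normexp the shared count was 7 higher and 0 lower, and PT over PBS gave 1.17 for Slc36a2, 0.76 for Aatk, 0.73 for Ces1f, 0.62 for Chil3, 0.61 for Klra5, 0.59 for Mgll and 0.50 for Apoc4. With the mean over probes it gave 0.44 for Klra5, -0.80 for Cmpk2 and -1.59 for Tgtp2, and with normexp Dusp2 was at -0.36 and -0.35, while Cmpk2 was at -0.43 and Erap1 at -0.26 with daidzein present.

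Daidzein over PBS addresses the isoflavone alone, and its differences in adipocyte genes were the larger of the 2 treatments. All 31 PPARg target and mature adipocyte genes were above 0, with a median of 4.2-fold (log2 2.07, percentile 100), and 21 of 29 were at least 2-fold higher. The fatty acid transporter Cd36 had a log2 difference of 3.19, the lipid-droplet protein Cidec 3.10, Gpd1 2.98 and Cfd 2.95. The transcription factors of adipogenesis as a list had a median of 0.04 (18 genes, percentile 89.0), yet Cebpa (1.53), the LXR gene Nr1h3 (1.30), Klf15 (1.12) and Pparg itself (1.03) were at least 2-fold higher. Lipolysis and lipid droplet genes had a median of 0.87 (percentile 100), adipokines 0.71 (percentile 100, with Cfd at 2.95, Retn at 2.5, Adipoq at 2.31 and Nrg4 at 2.04) and LXR-target cholesterol efflux genes 0.68 (10 genes, percentile 100). Fatty acid synthesis genes had a median of 0.48 and cholesterol synthesis genes 0.42, both at percentile 100. Oxidative phosphorylation genes were above 0 in 30 of 30 cases with a median of 0.27 (percentile 100), and fatty acid oxidation genes had a median of 0.18 (24 genes, percentile 100). Cell cycle and DNA replication genes were below 0 in 27 of 28 cases, with a median of -0.42 (percentile 0), among them Bub1b (-0.77), Kif11 (-0.65), Ccnd1 (-0.64) and Cdc20 (-0.62). Interferon-response genes had a median of -0.49 (21 of 23 below 0, percentile 0), and preadipocyte and fibroblast genes -0.18 (23 genes, percentile 0.03), with Ly6a at -0.80. Counted over all genes, 208 of 18915 were at least 2-fold higher and 70 at least 2-fold lower. With normexp these counts were 116 and 16, and the adipokine median was 0.29 (0.35 without its largest member, 0.20 with no filter on dim probes). The LXR-target median was 0.28 with no filter.

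With PT already present, daidzein gave a median of 1.90 over the same adipocyte list, with 31 of 31 genes above 0 (daidzein+PT over PT). The genes with the largest difference in both daidzein pairs, given with PT absent and then present, were Arxes1 (3.73 and 3.15), the resistin-like protein Retnla (3.06 and 4.13), the acute-phase glycoprotein Orm2 (3.05 and 2.94), Mgll (2.93 and 2.96) and the cytochrome oxidase subunit Cox8b (2.87 and 2.98). Cd36 (3.19 and 2.77), Cfd (2.95 and 2.70), Slc2a4 (2.60 and 2.72), the cytochrome P450 Cyp2e1 (2.96 and 2.52) and the scavenger receptor Marco (2.51 and 2.53) completed the 10 highest. The lowest were the matricellular protein Smoc2 (-2.17 and -1.86), the imprinted non-coding RNA H19 (-2.91 and -1.79), the troponin Tnni2 (-1.76 and -2.15), Ifi27l2a (-1.66 and -1.70) and Sapcd1 (-1.58 and -1.45). The stromelysin Mmp3 (-1.48 and -1.44), Cox6a2 (-1.52 and -1.36), Mamstr (-1.31 and -1.52) and Inmt (-1.33 and -1.25) followed. In this pair 388 genes were at least 2-fold higher and 158 at least 2-fold lower, against 233 and 41 with normexp. Among the 18256 genes read on all 4 arrays, 196 and 340 were at least 2-fold higher in the 2 daidzein pairs and 163 in both, where independent lists would share 3.65; 30 were at least 2-fold lower in both, where independent lists would share 0.47; across genes, Pearson's r was 0.62. With normexp these shared counts were 104 and 10, and the 2 differences were 1.31 and 2.67 for Retnla, 0.98 and 1.44 for Marco, -0.79 and -0.68 for Sapcd1, -0.55 and -0.49 for Inmt and -0.52 and -0.42 for Mamstr. With PT absent, Mgll was at 1.95 and Cox8b at 1.91 with normexp, and with PT present H19 was at -1.0 with the mean over probes.

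Daidzein+PT over PBS gave the largest medians of the 3 treated arrays in the adipocyte, sterol, fatty acid and interferon lists. PPARg target and mature adipocyte genes had a median of 7.62-fold (log2 2.93, 31 of 31 above 0), and 24 of 29 were at least 2-fold higher. The highest named genes were Retnla (4.69), Arxes1 (4.66), Mgll (4.17), Cd36 (4.07), Cox8b (4.07), Slc2a4 (4.06), Orm2 (4.06), the sulfate transporter Slc13a4 (4.05), Mrap (3.99) and Gpd1 (3.83). Cebpa (2.49), Klf15 (2.22), Nr1h3 (2.16) and Pparg (1.80) were higher, while the Kruppel-like factor Klf5 was lower (-1.03). Lipolysis and lipid droplet genes had a median of 1.38, adipokines 1.28, LXR-target genes 1.14, cholesterol synthesis genes 0.89, fatty acid synthesis genes 0.78, oxidative phosphorylation genes 0.54 and fatty acid oxidation genes 0.34, each at percentile 100. In cholesterol synthesis 9 of 23 genes were at least 2-fold higher, including Insig1 (1.68), Idi1 (1.47), Dhcr7 (1.25) and Lss (1.23). Interferon-response genes had a median of -0.97 with 0 of 23 above 0 and 11 at least 2-fold lower; Ifit3 (-1.53), Oas1a (-1.40), Rsad2 (-1.32) and Mx1 (-1.30) were the lowest. The lowest named genes outside that list were H19 (-2.19), Tnni2 (-1.97), Smoc2 (-1.89), Mmp3 (-1.62), the leukotriene-pathway protein Alox5ap (-1.59), the growth-cone protein Gap43 (-1.58), Slfn8 (-1.53) and Ifi27l2a (-1.49). Preadipocyte and fibroblast genes had a median of -0.25 (percentile 0.01), with 0 of 23 at least 2-fold lower, and extracellular matrix genes -0.17 (30 genes, percentile 0.01), with Mmp3 and Mmp9 (-1.14) the 2 members at least 2-fold lower. Over all genes, 466 of 18461 were at least 2-fold higher and 101 at least 2-fold lower, against 287 and 36 with normexp. With normexp the order of the highest genes differed (Retnla 2.65, Cox8b 2.98, Mgll 3.05, Cd36 3.83, Slc2a4 3.85), Alox5ap was at -0.99, Slfn8 at -0.83 and Gap43 at -0.69, and the adipokine median was 0.84; the LXR-target median was 0.73 without its largest member and 0.55 with no filter.

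**Figure D2:**
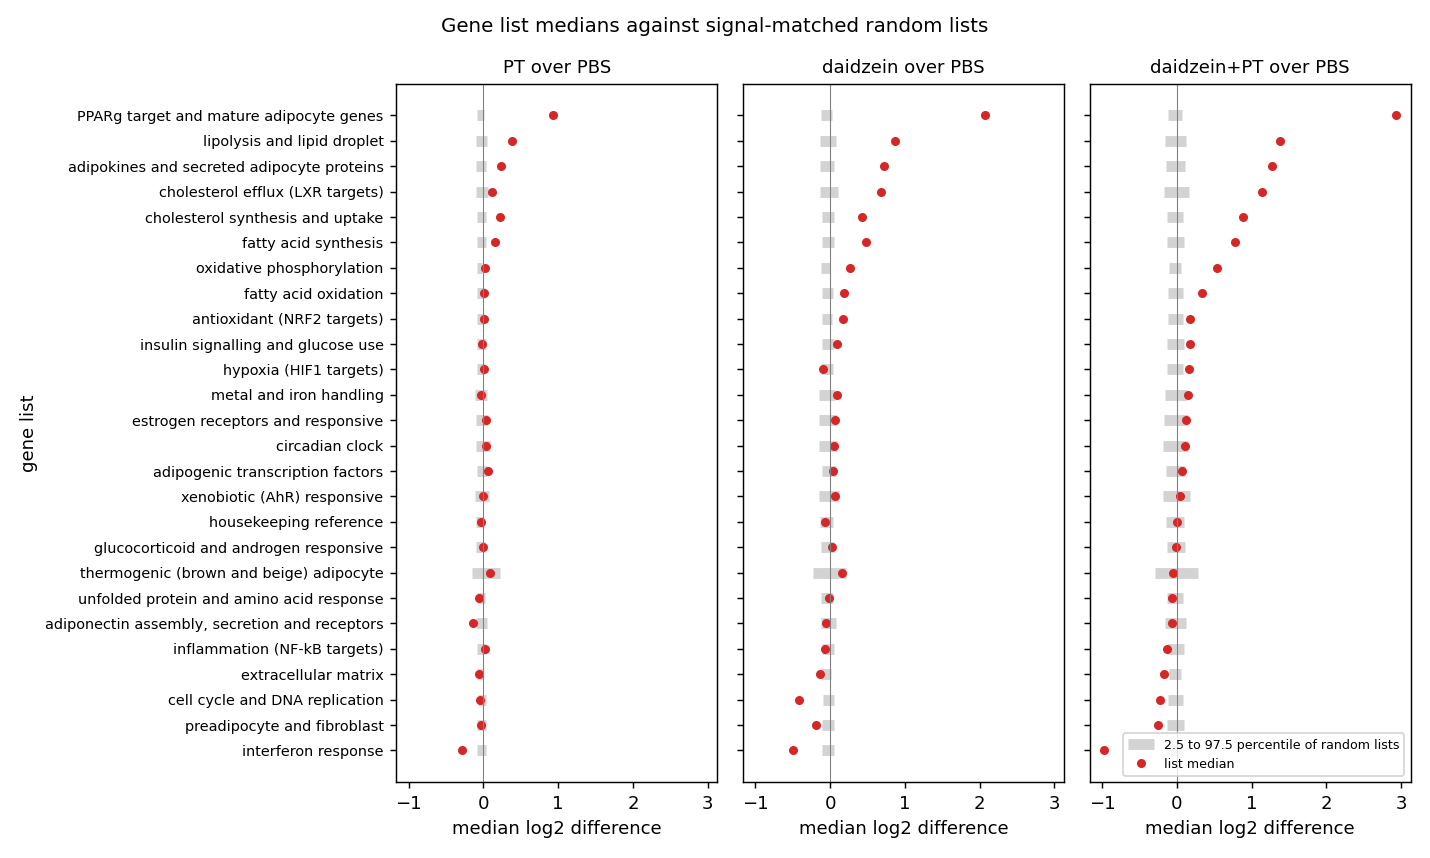
Median log2 difference from the PBS array (x axis) of each of the 26 gene lists (y axis) for the PT, daidzein and daidzein+PT arrays; red points are list medians and grey bars the middle 95% of 10000 random lists matched on signal. The PPARg target list lies at 0.93, 2.07 and 2.93 and the interferon list at -0.29, -0.49 and -0.97.

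Whether PT acted alike with and without daidzein is the question of the interaction, which was computed without a test. It sets the PBS and daidzein+PT arrays (slide columns 3 and 2) against the daidzein and PT arrays (columns 4 and 1). A difference between inner and outer columns therefore cannot be told apart from a dependence of 1 treatment on the other. Members of the PPARg target list lay on both sides of additivity, with an interaction median of -0.10 (15 genes above 0 and 16 below, percentile 0), with Aqp7 at 0.83, Gpd1 at -0.61 and Cidec at -0.72 among members well above background on all 4 arrays. Lists of lipid synthesis and transport had positive medians: LXR-target genes 0.27 (10 of 10 above 0, percentile 100), fatty acid synthesis genes 0.22 (16 of 20) and cholesterol synthesis genes 0.19 (21 of 23), with Fdps at 0.63. The interferon list had -0.09 (15 of 23 below 0, percentile 0.01). Cell cycle genes had an interaction median of 0.18 (26 of 28 above 0, percentile 100). Their median was -0.04 for PT alone (percentile 21.8) and 0.20 for PT added to daidzein (percentile 100), as for Birc5 (-0.09 and 0.36) and Tk1 (0.07 and 0.34). Oxidative phosphorylation genes had an interaction median of 0.27 (29 of 30 above 0, percentile 100), from 0.03 for PT alone (0.08 under cyclic loess) to 0.28 with daidzein present, as for Cycs (0.16 and 0.59) and Uqcrfs1 (0.17 and 0.52). HIF1 target genes had 0.17 (18 of 21 above 0, percentile 99.9), with Egln3 at 0.09 and 0.78 and Bnip3 at 0.02 and 0.69. Of 18256 genes, 125 had a 2-fold or larger positive interaction and 120 a negative one, and 235 of these 245 were among the dimmest 6086 genes. These counts were 28 and 9 with normexp and 180 and 181 with the mean over probes. The most positive named genes were Bicra (3.29), Baiap2l1 (2.90), Gng13 (2.78), Nsrp1 (2.78) and Trim71 (2.71), each highest on the daidzein+PT array. The most negative were Nxf2 (-2.59), Ebna1bp2 (-2.52), Lmod3 (-2.49), Ctrc (-2.15) and Olfr482 (-2.14). The 3 probes of Ebna1bp2 disagreed, from -0.63 to 2.66 for daidzein+PT over PBS, and their mean had an interaction of -0.93. With normexp the interaction was 1.69 for Bicra, 1.63 for Baiap2l1, 1.5 for Trim71, 1.45 for Nsrp1, 1.18 for Gng13, -1.40 for Nxf2, -0.88 for Olfr482, -0.76 for Lmod3 and -0.66 for Ctrc.

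The effects of the 2 treatments were averaged over both pairs and compared across 18256 genes. Both averages come from the same 4 arrays, so noise of an array enters both, and the counts that would arise without a shared response were not worked out. Of the 300 genes most raised on average with daidzein, 293 were also above 0 with PT, with a PT median of 0.59. Of the 300 genes most lowered with daidzein, 138 were below 0 with PT, with a PT median of 0.03. In limma's additive fit of both treatments, with 1 residual degree of freedom, 554 of 19568 genes passed an adjusted p of 0.05 as higher and 110 as lower with PT, and 1685 and 1346 with daidzein. Adipoq had a log2 estimate of 0.96 for PT and 2.19 for daidzein in that limma fit. Its standard error of 0.08 rests on variance pooled over genes and does not measure spread between cultures. With the trend kept, fewer genes passed under quantile normalization, cyclic loess, normexp, the authors' values and the mean over probes, as given below. These calls rest on the modelled trend of variance with signal: without the trend limma called 11 and 0 genes for PT and 0 and 0 for daidzein, with 1457 and 3412 genes at an unadjusted p under 0.05.

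**Figure D3:**
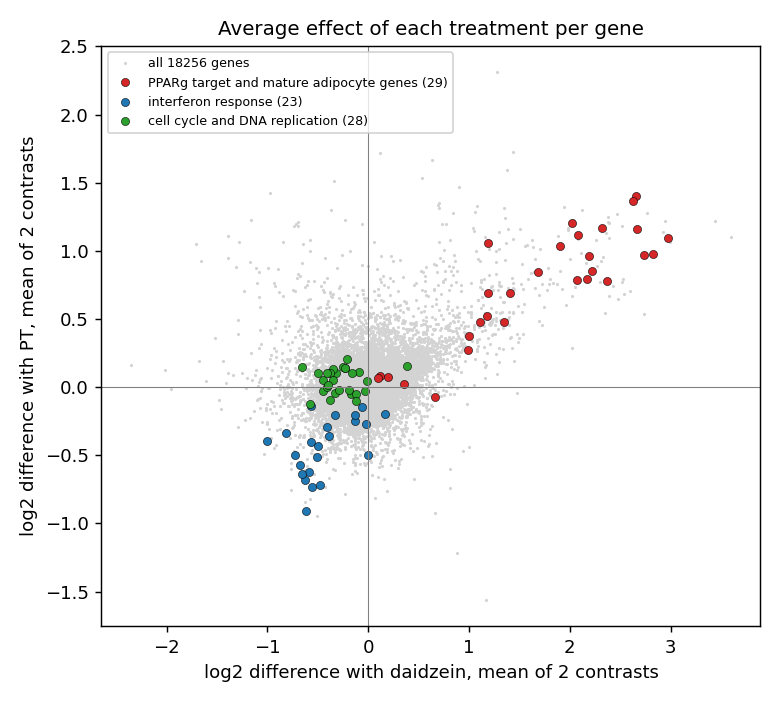
Average log2 difference with daidzein (x axis) against that with PT (y axis), each the mean of 2 pairs of arrays, for 18256 genes (grey) with the PPARg target, interferon-response and cell cycle lists marked. The PPARg target list has medians of 1.99 with daidzein and 0.84 with PT, and the interferon list -0.51 and -0.40.

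Several lists tied to adipocyte function lay closer to 0. Genes of adiponectin assembly, secretion and receptors had medians of -0.14 with PT (percentile 0.18), -0.05 with daidzein and -0.07 with both (13 genes, none at 2-fold; -0.08 with PT for the mean over probes, -0.02 with daidzein under cyclic loess and -0.11 with both under quantile normalization), with Cdh13 (T-cadherin) at -0.73 and Plod1 at -0.37 on the daidzein+PT array. Insulin signalling and glucose use genes had medians of -0.02, 0.09 and 0.17 (20 genes, percentile 99.9 with both, the sign for PT turning under quantile normalization and cyclic loess), where Slc2a4 (4.06), Pfkfb3 (1.38) and the hexokinase Hk2 (1.06) were at least 2-fold higher with both. Thermogenic adipocyte genes had medians of 0.09, 0.16 and -0.05 (9 genes); the median for daidzein turned sign with no filter (-0.005), and that for both turned sign under cyclic loess, under normexp, with genes above background on all 4 arrays (0.10) and with no filter (0.34). In this list Cox8b and Cox7a1 (1.97) were higher with both treatments while Dio2 was at -0.48. Antioxidant genes had medians of 0.01, 0.17 and 0.18 (22 genes, percentile 99.9 with both), with Gsta3 at 2.31 and Me1 at 1.15. Metal and iron handling genes had 0.15 with both (12 genes, percentile 98.2), led by the transferrin receptor Tfrc (0.72). NF-kB target genes had 0.01, -0.06 and -0.13 (21 genes, percentile 3.27 with both, the sign for PT turning under quantile normalization, cyclic loess and normexp; -0.14 to -0.03 with both over the alternatives), with Lcn2 at 2.45 and C3 at 0.89 against Saa3 at -0.65. Unfolded protein and amino acid response genes had -0.06, -0.01 and -0.06 (21 genes, the sign for daidzein turning under quantile normalization and cyclic loess), all within the range of random lists.

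Reference genes differed little, with list medians of -0.03 for PT, -0.07 for daidzein and 0.00 for both (15 genes), signs that turn under some of the other scalings. Gapdh differed from PBS by -0.03, -0.10 and 0.19 and Actb by -0.11, -0.09 and -0.01. Markers of other cell types were mostly not well above background. Of the macrophage markers 8 were measured, of the endothelial 4, of the myogenic, osteogenic and chondrogenic 3, of the testis germ cell 6 and of the Sertoli and Leydig cell 4. Their medians against PBS lay within the range of random lists on all 3 treated arrays. For the germ cell list they were 0.01 with PT and 0.49 with daidzein+PT (percentiles 39.6 and 93.7). The marker lists leave out genes named elsewhere for their differences, such as Retnla, the scavenger receptor Marco, Chil3 and the troponins Tnni2 and Tnnt3. Their medians therefore do not show that no gene of another cell type differed. For daidzein+PT over daidzein, macrophage markers had a median of -0.18 (7 of 8 below 0, percentile 1.22) and Sertoli and Leydig cell markers 0.23 (3 of 4 above 0, percentile 98.2). Each lay outside the range of random lists, in the pair where PPARg target genes had 0.80 and interferon-response genes -0.50. With 26 gene lists and 5 cell type lists in several comparisons, some lie outside that range without any shift, as 9 of 200 did in the simulation.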

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

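The tests of other probes in this part were chosen after the result was seen. In 2 unnamed transcribed regions a treatment difference ran in opposite directions with and without the other treatment, at 2-fold or more each way, and the difference between these differences was not tested. Independent lists would give 2.65 such genes for daidzein, where 2 were seen, and 0.18 for PT, where 1 was seen. For the region on chromosome 10 from 116814196 to 116920696 (mm9), PT gave a log2 difference of -1.26 without daidzein and 1.67 with it, and daidzein gave -1.30 without PT and 1.62 with it. For the region on chromosome 5 from 14943275 to 14944205, daidzein gave -1.12 without PT and 1.28 with it. Both were dim, with an SD of 0.33 for a difference. Both had more signal on the PBS and daidzein+PT arrays (slide columns 3 and 2) than on the daidzein and PT arrays (columns 4 and 1). Slide column therefore cannot be told apart from the treatments here. The other probe of the chromosome 10 region gave -0.39 and 1.68 for PT and -0.84 and 1.24 for daidzein, and that of the chromosome 5 region gave -1.26 and 1.43 for daidzein.

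Among the 245 genes with an interaction of 2-fold or more, 41 had another probe that was read, and in 20 of 41 that probe shared the sign of the interaction. The upper exact 95% limit of this share was 64.9%, against 95.2% (40 of 42) for genes at 2-fold in both pairs of a treatment, which were chosen for agreeing. For genes at 2-fold in a single PT pair the share was 74.1% (53.7 to 88.9) without daidzein and 67.9% (47.7 to 84.1) with it; these limits overlap those of the interaction (32.9 to 64.9), so a response to PT that daidzein alters stays open. Departures of single dim probes may account for many of these values, as a hypothesis found and tested on the same arrays. The 3 genes whose other probe was also at 2-fold in the same direction, which include both regions above, and the genes with no other probe stay open.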

How the results depend on the processing

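The restriction to the brighter genes was chosen after the data were seen. Counts are given for PT over PBS, daidzein over PBS, daidzein+PT over PBS, daidzein+PT over daidzein and daidzein+PT over PT, then for both PT pairs and both daidzein pairs, then for the interaction. The cause of each shift was not tested, except that thresholds and filters change counts by their construction. With normexp the counts higher were 42, 116, 287, 65 and 233, then 7 and 104, then 28 positive, and lower 1, 16, 36, 2 and 41, then 0 and 10, then 9 negative. With no filter they were 2197, 1786, 2669, 2083 and 2045, then 420 and 446, then 2483 higher, and 884, 1154, 1041, 1088 and 1778, then 101 and 175, then 2674 lower. At 1.5-fold they were 501, 586, 1117, 604 and 936, then 125 and 362, then 441 higher, and 121, 460, 544, 156 and 665, then 12 and 177, then 541 lower. At 3-fold they were 47, 85, 235, 55 and 161, then 2 and 67, then 33 higher, and 1, 9, 5, 4 and 39, then 0 and 4, then 28 lower. In the brighter genes alone (upper 2 of 3 equal parts by signal) they were 42, 109, 222, 32 and 163, then 13 and 97, then 4 higher, and 1, 20, 49, 0 and 38, then 0 and 11, then 6 lower. Genes lower for PT over PBS numbered 30 with quantile normalization, 29 with the authors' values and 22 with the mean over probes, which also gave 181 negative interactions.

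In the additive limma fit, genes called higher with PT numbered 200 with quantile normalization, 215 with cyclic loess, 324 with normexp, 202 with the authors' values, 165 with the mean over probes, 1660 with no filter and 11 without the trend. Genes called lower with PT numbered 23, 20, 58, 23, 14, 364 and 0 in the same order, and 193 with median scaling. For daidzein the mean over probes gave 950 higher and 626 lower, cyclic loess 846 lower, and limma without the trend 0 higher and 0 lower, with 3412 genes at an unadjusted p under 0.05.

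The PPARg target list had a PT median of 0.88 with quantile normalization, 0.65 with normexp and 0.88 with the authors' values. Its daidzein median was 2.12 with cyclic loess, 1.39 with normexp, 1.87 with the mean over probes and 1.91 without its largest member, and its median with both was 2.22 with normexp, 2.74 with the mean over probes and 2.85 with genes above background on all 4 arrays. The interferon list had a PT median of -0.25 with cyclic loess. Its daidzein median was -0.44 with the mean over probes, with no filter and without its largest member, and its median with both was -0.91 with normexp and -1.03 with the mean over probes.

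Adipoq stayed within its spread in 40 of 40 values over the alternatives fixed beforehand, but not all of these could move. Changes of filter left the value of a named gene as it was. Adipoq has only 1 probe, so the mean over probes also repeated its main value. The authors' values nearly repeated quantile normalization (1.119 and 1.12 for Adipoq with PT over PBS). Of 800 values of named genes, 0 took the opposite sign and 74 moved beyond the spread. These 800 include the values under changes of filter, which could not move. Of 702 list medians 51 took the opposite sign, none for a list outside the range of random lists. Leaving out an array and other splits of the samples do not apply, since with 1 array per group the additive fit minus an array has no residual degree of freedom. Signal over background limits the results most directly in the dim genes: 13190 of 34795 genes were well above background on no array.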

Other observations

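The tests of a general shift, shares of cells and cultures in this part were chosen after the result was seen, and those of the scaling before. Daidzein is an isoflavone with estrogenic activity, and PT comes from a steroid-producing organ, so hormone-responsive lists were among those fixed. Estrogen-responsive genes had medians of 0.04 with PT, 0.07 with daidzein and 0.12 with both (13 genes, percentiles 91.1, 93.7 and 96.0), with a range of 0.06 to 0.34 for both over the alternatives and the sign for PT turning without its largest member (-0.004). The list lay above the range of random lists for daidzein+PT over daidzein (0.15, percentile 99.4), for daidzein+PT over PT (0.17, percentile 98.2) and for the interaction (0.20). In that list Greb1 was at 1.47 with daidzein and 2.18 with both, and the corepressor Nrip1 at 0.72 and 1.16. Glucocorticoid and androgen responsive genes had medians of -0.01, 0.03 and -0.01 (17 genes, ranges over the alternatives -0.01 to 0.05, -0.001 to 0.10 and -0.04 to 0.02, so each sign turned under some), with the cortisol-regenerating enzyme Hsd11b1 at 0.72, 1.56 and 2.53. Xenobiotic-responsive genes had -0.01, 0.07 and 0.05 (8 genes, ranges over the alternatives -0.02 to 0.04, 0.03 to 0.20 and 0.02 to 0.34, the sign for PT turning), with Cyp2e1 at 3.28 and Cyp2f2 at 1.57 with both treatments. Circadian clock genes had 0.03, 0.05 and 0.11 (15 genes, ranges -0.01 to 0.09, 0.01 to 0.12 and 0.07 to 0.16, the sign for PT turning), with Ciart at 1.32 and Per2 at 0.89 with both.

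Some genes were well above background on only 1 array of a pair, so their differences are bounds. For PT without and with daidzein, Osta was at least 8.86-fold and 8.03-fold higher, Neurog1 at least 6.94-fold and 5.03-fold, and the olfactory receptor gene Olfr152 at least 5.99-fold and 6.59-fold. These 3 genes were dim on the arrays with PT (-1.31 to -2.11). Bounds of 2-fold in both PT pairs numbered 16 higher and 0 lower. Both arrays with PT lay in slide row 2, so slide position cannot be told apart from PT here. For daidzein without and with PT, Tmem45b was at least 7.91-fold and 14.3-fold higher, Zfp704 at least 8.98-fold and 4.90-fold, and Rassf6 at least 4.51-fold and 6.92-fold. On the lower side for daidzein were the fast skeletal troponin Tnnt3 (at least 3.29-fold and 3.11-fold), the complement inhibitor Serping1 (2.81-fold and 2.08-fold) and the retinol transporter Stra6 (2.04-fold and 2.43-fold).

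For the adipocyte genes that were higher with each treatment, the range of signal-matched random lists reached 0.096 at most in the 4 pairs (spike-ins 0.14). The smallest median of the PPARg target list was 0.805. The scaling beforehand removes a shift common to all genes, so this comparison cannot tell whether labelling or slide position shifted an array. It shows only that the list differed by more than genes of like signal did after the scaling. An effect of slide position on these probes alone cannot be told apart from PT. Under quantile normalization, cyclic loess, median scaling and the authors' values the list kept at least 0.942 of its median. That argues against the choice among these scalings, none of which was set by the spike-ins. Normexp, a background correction not counted among these, lowered the median to 0.65 with PT and 1.39 with daidzein, so its size depends on the background correction. A larger share of differentiated cells stays open: the ratio of PT to daidzein differences had a quartile width of 0.143 over members, against at most 0.132 in the middle 95% of simulated array noise. Around the list's ratio of 0.281, noise gave medians of 0.148 to 0.434 for oxidative phosphorylation genes, where 0.076 was seen. Cell cycle (0.187) and preadipocyte genes (0.094) lay within their own ranges. The oxidative phosphorylation PT median itself ran from 0.02 to 0.08 over the alternatives. An interaction of -0.10 for the PPARg target list is small beside that list's medians. It goes against a single culture set apart from the rest, unless true non-additivity offset it. Differences among several cultures cannot be told apart from treatment with 1 array per group.

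The lower interferon-response genes were weighed against the same change in the share of cells. The ratio of PT to daidzein differences had a median of 0.882 (quartiles 0.611 and 1.29) in this list, against 0.281 (quartiles 0.211 and 0.354) in the adipocyte list. These quartiles did not overlap, while those of the daidzein+PT to daidzein ratio did (medians 1.72 and 1.995); a single change in share needs equal ratios of both kinds, so the first argues against 1 change in the share of differentiated cells behind both lists. Under the same scalings the interferon list kept at least 0.879 of its median, which argues against the choice among these scalings. All of them align the bulk of genes, so they cannot tell whether a scaling by the spike-ins would shrink the median. Random lists reached 0.103 below 0 at most in the 4 pairs, against 0.287 for the smallest interferon median. As for the adipocyte list, the scaling beforehand keeps this comparison from telling whether all signal shifted. Spike-ins differed by -0.14 for PT over PBS, where the interferon median was -0.287, and a scaling by the spike-ins was not tried. An effect of slide position on the interferon probes alone cannot be told apart from PT.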
